A study of Xenopus laevis with 12 samples.

How the data were processed

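Gene expression was measured in explants of embryonic ectoderm (animal caps) of the frog Xenopus laevis on 12 one-colour Affymetrix genome arrays. Per the labels' protocols, a Geminin RNA named as a form without its coil was injected at 300 pg into the animal hemisphere of both cells of 2-cell embryos. Whether 300 pg is the amount per cell or per embryo is not given in the sources used here. Caps were cut at stage 8 to 9, 80 per sample, and kept in 0.7x MMR, a salt solution, at 25 °C until sibling embryos reached stage 10.5 or stage 12, when 20 µg of total RNA was isolated. The controls are uninjected explants. Arrays of explants injected with a control RNA were not analysed here, so effects of injection itself are part of every injected against uninjected difference.

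The authors deposited 1 value per probe set and array, as an intensity on a linear scale. The summary algorithm, background correction and scaling are not given in the sources used here. The deposited array medians ranged over 1.31 on the log2 scale, while the medians of the arrays of a pair lay within 0.04 of each other. Because the medians differed by more than 0.2, the limit set before the data were examined, log2(intensity + 16) was quantile normalised across the arrays, and the deposited scale was kept as an alternative. Fold changes are on this log2(intensity + 16) scale, which understates the change of dim genes. Of 15491 probe sets, the 3873 in the lowest 25% of mean signal were left out and 11618 were tested. Of the probe sets used, 0 were named as Affymetrix controls. The number of arrays limits the precision.

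The probe annotation gave 1 gene symbol for 9304 probe sets, several for 195 and none for 5992, and only probe sets with 1 symbol are named. Symbols were updated through gene identifiers, which matched for 9227 probe sets and changed 2 symbols. No genome build is named for the array, so no positions are given. The suffixes .L and .S mark the copies of a gene on the long and short chromosomes of this allotetraploid frog, and probes can cross-hybridise between copies. Of the named genes tested, 984 had several probe sets.

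Samples were grouped by title and by the stage and manipulation labels. The description of the uninjected stage 12 array of experiment 2 names stage 10.5, and its title and stage label were followed. Its profile correlated at 0.99 with the library labelled uninjected, stage 12, experiment 3. The design text says that injected and uninjected samples were paired and that the entire experiment was repeated 3 times per stage. Deviations from the group means of same-numbered injected and uninjected arrays correlated at 0.765 to 0.797 at stage 10.5 and at 0.424 to 0.693 at stage 12. At stage 12, arrays of experiments 2 and 3 also deviated together, at 0.497 and 0.555. Injected experiment 3 deviated more with uninjected experiment 2 (0.555) than with its own partner (0.424). The deviations thus do not bear out the pairing of these 2 experiments. Following the design text, the experiment within a stage was a block in the fits of injected against uninjected explants. Experiment numbers did not link the stages (correlations of -0.04 to 0.17), and the uninjected stages were compared without a block.

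Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 12 arrays, with Benjamini-Hochberg adjustment over the 11618 probe sets and a threshold of 0.05. The paired fits have 4 residual degrees of freedom and the stage comparison has 8. Each SE given is limma's, from 1 spread per probe set shared by all groups of the fit. A count without a model took probe sets changed at least 1.5-fold the same way in all 3 pairs. The 20 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and 1 probe set per gene (the brightest). The .L and .S copies of a gene count as separate genes in the lists, so counts of listed genes can hold a gene in both copies. Lists share members, so their results are not independent. The msx1 and id3 genes are in both neural crest and BMP response, and ventx2 genes in both BMP response and pluripotency. The myc genes are in both neural crest and Wnt response, and ccnd1 genes in both Wnt response and mitotic cell cycle. Both epidermis and BMP response hold gata2.L and gata3.S, and foxi1.L is in both epidermis and multiciliated cells and ionocytes. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. The genes named are the geminin probe sets, the 10 largest rises and 10 largest falls of each injected against uninjected comparison (adjusted p below the threshold, the same sign in all 3 pairs, 1 informative symbol), 5 per direction for the difference between stages and for the uninjected stages, and up to 4 members with the smallest p of each list.

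Other alternatives were no block, no filter or a filter on the lowest 50%, pseudocounts of 1 and 64, median centring, other variance models, a 2-fold limit, fits of the compared groups alone, and fits without each replicate. Each fit was tested on simulated arrays with the real means and spread of 11618 probe sets and 200 changed ones. Pair effects were simulated for the paired fits only. For stage 10.5, 41.8% of 1.5-fold, 95.5% of 2-fold and 100% of 3-fold changes were recovered. For stage 12 the shares were 26.9%, 97% and 100%, for the difference between stages 4.48%, 61.2% and 97%, and for the uninjected stages 0%, 25.4% and 78.8%. False calls made up 7.6%, 4.49%, 9.24% and 6.76% of the calls in these simulations, in that order. Fewer probe sets were changed than passed in the real data, and the adjusted threshold depends on that share. The recovered shares thus do not carry over to the real fits. Noise was independent between arrays, so arrays as similar as those of stage 12 experiments 2 and 3 were not simulated. Figures were drawn with matplotlib 3.10.9.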

Results

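RNA from 12 samples of Xenopus ectoderm explants was profiled, with 3 arrays in each of 4 groups: Geminin-injected and uninjected explants at stage 10.5 (early gastrula) and at stage 12 (late gastrula). Geminin restrains DNA replication licensing by binding Cdt1 and also takes part in early neural development. The injected RNA was the form named as without its coil, here called Geminin for short. Whether this form binds Cdt1 was not tested here. The series title gives the aim as finding genes that Geminin regulates in the embryonic ectoderm. Median deposited intensity per array ranged from 49.0 to 145.7.

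The injected gene was read first. The deposited intensity of gmnn.L was 5435, 10464 and 3446 in injected explants at stage 10.5, against 261, 233 and 375 in uninjected explants of the same experiments. At stage 12 it was 3203, 13754 and 13436 in injected explants, against 116, 278 and 4576. The library labelled uninjected, stage 12, experiment 3 thus carried far more gmnn.L signal than the other uninjected libraries, while its gmnn.S intensity of 250 was close to the 261 of experiment 2. In the paired limma fit gmnn.L rose by 4.60 ± 0.55 (SE, n = 3 pairs) on the log2 scale at stage 10.5 (adjusted p = 0.000305) and by 3.56 ± 0.55 at stage 12 (adjusted p = 0.000577). Both SEs rest on 1 spread that limma shares between the stages. The stage 12 SE and p thus do not show how unequal its 3 pairs were. The gmnn.S probe set rose by 1.09 ± 0.13 at stage 12 (adjusted p = 0.000114). Its value at stage 10.5 was 0.43 ± 0.13 (adjusted p = 0.0527).

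**Figure D1:**
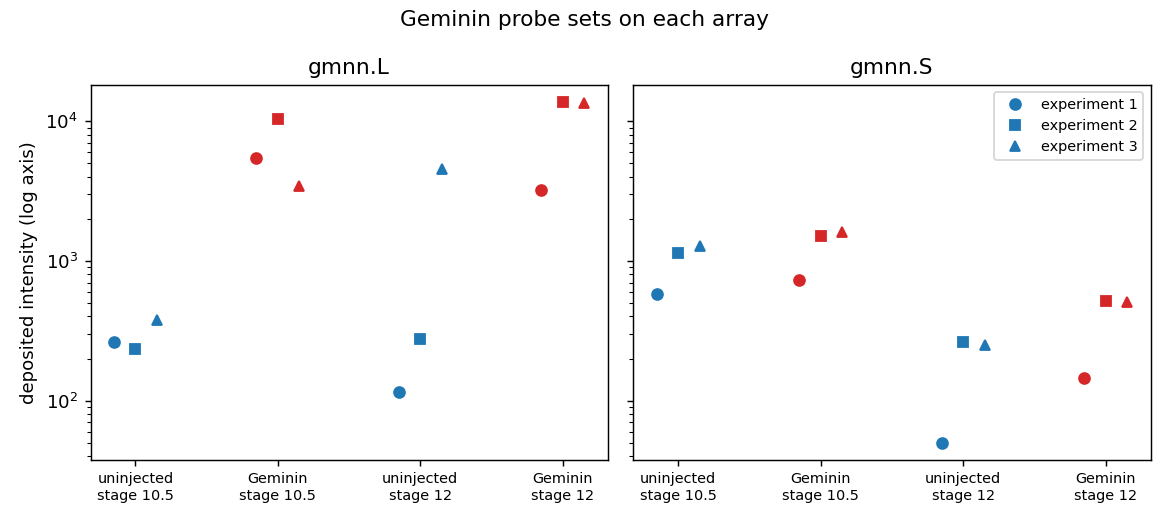
Deposited intensity (log axis) of the gmnn.L and gmnn.S probe sets on each of the 12 arrays, by group, with a symbol per experiment, injected in red and uninjected in blue. For gmnn.L, 5 of the 6 uninjected arrays lie between 116 and 375 and the library labelled uninjected, stage 12, experiment 3 lies at 4576.

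At stage 10.5 Geminin-injected explants had lower levels of genes of the epidermis and of the response to BMP, the signal that directs ectoderm towards epidermis, with 18 of 32 and 16 of 24 listed genes lower. The keratin krt70.L fell by 3.12 ± 0.26 (SE, n = 3 pairs) on the log2 scale, 8.71-fold. The BMP-responsive transcription factor gata2.L fell by 2.91 ± 0.26, and the secreted BMP regulator szl.L (sizzled) fell by 2.83 ± 0.24. The homeobox genes dlx3.S (-2.63), dlx3.L (-2.57) and msx1.L (-2.43) also fell. The other largest falls were in arg1.L (-2.84), gatm.L (-2.65), the keratin krt12.4.L (-2.56) and crx.S (-2.53). A second gatm.L probe set gave -0.19. Beside gmnn.L, the largest rises were in tsen54.L (1.84), the RNA-binding protein genes zfp36l2.1.S (1.75) and zfp36l2.2.L (1.60), rpain.S (1.53), oat.S (1.45), cat.2.L (1.37), btg4.L (1.36), dclre1a.L (1.31) and birc7-b (1.3). Further probe sets of tsen54.L gave 0.32 and 1.90, and a second one of cat.2.L gave 0.22. Adjusted p ranged from 4.56e-05 to 0.00501 over these genes.

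In limma's paired fit 1205 of 11618 probe sets passed at stage 10.5, 385 higher and 820 lower, all with the same sign in the 3 pairs. At least 2-fold changes were 65 higher and 357 lower. Without the replicate block 262 passed, 22 higher and 240 lower. Fits that left out the pair of experiment 1, 2 or 3 gave 535, 454 and 779. Without a model, 611 probe sets changed at least 1.5-fold the same way in all 3 pairs, 161 higher and 450 lower. In the pairs of experiments 1 and 2 alone 1016 did so. With the sign of 1 pair turned at most 3 did so, a count that is low wherever pairs move alike, whatever the cause.

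Of the 20 gene lists, 7 were shifted at stage 10.5 by camera at the preset correlation, all downwards. Some of these lists share members, so the 7 are not independent. With an estimated correlation 0 passed (4 at an unadjusted p under 0.05), and fry called 5. When the sign of the pair of experiment 1, 2 or 3 was turned, 0, 1 and 9 lists passed at the preset correlation. Among 32 epidermal genes 18 fell and none rose (22 fell and 1 rose adjusted over the list alone), with a median of -1.08 (adjusted p = 2.57e-17, adjusted p = 0.224 with an estimated correlation). Among 24 genes of the BMP response 16 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -1.02 (adjusted p = 8.13e-15, adjusted p = 0.224 with an estimated correlation). They included bambi.L, a BMP pseudoreceptor, which fell by 1.69. The 2 that rose were the copies bmp2.L (0.963) and bmp2.S (0.636). Of 15 neural crest and border genes 8 fell and 1 rose (9 and 2 adjusted over the list alone), with adjusted p = 6.39e-07 and adjusted p = 0.224 with an estimated correlation. They included prdm1.S (-2.09), id3 (-1.05) and pax3.L (-1.17), of which other probe sets gave 0.27 and -1.18. Of 16 neural plate genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with adjusted p = 0.000544 and adjusted p = 0.227 with an estimated correlation. Those that fell included irx1.L (-2.02), irx2.L (-1.91), the neural progenitor factor sox2.L (-1.38) and zic1.S (-1.16). Of 11 Wnt response genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with adjusted p = 0.00112 and adjusted p = 0.224 with an estimated correlation. The cyclin genes ccnd1.L (-2.19) and ccnd1.S (-1.97) fell, and myc.S rose by 0.79 (0.44 and 0.53 for other probe sets). Among those that did not pass were axin2.L (-0.298), axin2.S (-0.378) and znrf3.S (-0.249). Of 16 genes of pluripotency and uncommitted ectoderm 7 fell and 3 rose (8 and 4 adjusted over the list alone), with adjusted p = 0.00322 and adjusted p = 0.577 with an estimated correlation. They included sall1.L (-1.99) and pou5f3.1.L (-1.34). Of 69 ribosomal protein genes 17 fell (22 adjusted over the list alone) with a median of -0.12, adjusted p = 1.19e-06 and adjusted p = 0.577 with an estimated correlation.

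The remaining 13 lists did not pass at stage 10.5. Their camera adjusted p was 0.222 for multiciliated cells and ionocytes, 0.363 for germ plasm, 0.367 for neuronal differentiation and for the mitotic cell cycle, 0.404 for FGF response, DNA replication and interferon response, 0.418 for p53, 0.571 for organizer, 0.745 for Polycomb, 0.876 for mesoderm and endoderm and 0.959 for Hox. Single members passed, among them dll1.L, a Notch ligand gene (-2.41), gadd45g.L (-2.21) and, upwards, the muscle factor myod1.L (0.84). Median, mean and test differed in sign for p53 (median 0.18, mean -0.19, test down), for endoderm (0.07, -0.02, down) and for Hox (-0.05, 0.04, up).

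At stage 12 the largest rises included genes of the cell division machinery, with 25 of 50 listed mitotic genes higher, and the largest falls included genes of ciliated cells and ionocytes, with 9 of 11 listed genes lower. The mitotic cyclin ccnb1.S rose by 3.36 ± 0.27 (SE, n = 3 pairs), 10.3-fold, ccna1.L by 2.48, ccna1.S by 2.02 and wee2.S, a kinase gene that restrains entry into mitosis, by 2.01. The POU factor pou5f3.3.L rose by 2.31, tsen54.L by 3.29, pc.1.L by 2.48, tmem169.L by 2.15 and sesn1.L by 2.04. Further probe sets gave 0.46 and 2.68 for tsen54.L and -0.23 for pc.1.L, while a second hunk.L probe set gave -1.71 and a second fzd10.S probe set -1.21. Genes that fell included rsph1.L (-3.12 ± 0.29) and cfap52.S (-2.72), both of ciliary structures, the ionocyte factor ubp1.L (-3.01), dlx2.L (-2.82), the Wnt receptor gene fzd10.S (-2.69), tbc1d24.2.L (-3.24), slc38a2.L (-3.12), tnni2.S (-3.03), plpp3.S (-2.89) and hunk.L (-2.72). Injected plpp3.S was at 4.32 (log2), under the 5th percentile of all probe sets of 4.43, so low signal bounds its fall. Adjusted p over these genes ranged from 6.59e-06 to 0.000172.

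In limma's paired fit 4781 of 11618 probe sets passed at stage 12, 2733 higher and 2048 lower, and 4718 had the same sign in all 3 pairs. The excess of rises depended on the scaling, with 2238 higher and 2275 lower on the deposited scale and 2361 and 2188 with median centring. At least 2-fold changes were 440 higher and 768 lower. Without the replicate block 1509 passed, 615 higher and 894 lower. Without the block and without the library labelled uninjected, stage 12, experiment 3, an alternative chosen after seeing the data, 1162 passed. Without a model, 1469 probe sets changed at least 1.5-fold the same way in all 3 pairs, 540 higher and 929 lower. In the pairs of experiments 1 and 2 alone 2458 did so. With the sign of 1 pair turned at most 8 did so, a count that is low wherever pairs move alike, whatever the cause. Arrays of experiments 2 and 3 were closely similar at stage 12 (r = 0.990 uninjected, 0.982 injected), and whether they came from separate batches of embryos is not given in the sources used here, so SEs and p at stage 12 could rest on fewer than 3 independent pairs. With these pairs averaged into 1, an alternative chosen after seeing the data, 4085 passed.

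At stage 12 camera at the preset correlation shifted 7 lists, 6 downwards and 1 upwards. Some of these lists, too, share members. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), and fry called 13. When the sign of the pair of experiment 1, 2 or 3 was turned, 1, 8 and 6 lists passed at the preset correlation. Of 32 epidermal genes 24 fell and 1 rose (27 and 1 adjusted over the list alone), with a median of -1.23, adjusted p = 3.83e-12 and adjusted p = 0.239 with an estimated correlation. They included agr2.S (-2.51), the lectin itln1.L of mucus-secreting cells (-2.53) and ppl.L (-2.14). Of 24 BMP response genes 22 fell and 2 rose, also adjusted over the list alone, with a median of -1.17, adjusted p = 5.87e-11 and adjusted p = 0.239 with an estimated correlation. They included gata3.S (-2.39), msx1.S (-2.0), id2.L (-1.08) and id4.S (-1.47). The 2 that rose were the copies bmp2.L (0.727) and bmp2.S (0.517). Of 15 neural crest and border genes 12 fell, also adjusted over the list alone, with adjusted p = 1.68e-07 and adjusted p = 0.239 with an estimated correlation. They included myc.L (-1.59), pax3.L (-1.44, with -0.21 and -1.21 for other probe sets) and kctd15.L (-1.87). Of 11 genes of multiciliated cells and ionocytes 9 fell and 1 rose, also adjusted over the list alone, with a median of -1.53, adjusted p = 6.05e-07 and adjusted p = 0.239 with an estimated correlation. They included foxn4.S (-1.56), ca12.L (-1.39) and ccno.L (-1.75). Of 69 ribosomal protein genes 22 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.17, adjusted p = 2.58e-05 and adjusted p = 0.416 with an estimated correlation. Of 11 Wnt response genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with adjusted p = 0.0252 and adjusted p = 0.239 with an estimated correlation. Those that fell were ccnd1.L (-1.85), ccnd1.S (-1.76), meis3.S (-1.71), myc.L (-1.59) and myc.S (-0.917), and tcf7.S rose by 1.52. Those that did not pass were axin2.L (0.225), axin2.S (0.23), znrf3.S (0.191), sp5l.S (-0.059) and meis3.L (-0.509). Without the pair of experiment 3 this list did not pass (camera adjusted p = 0.0655). Of 50 mitotic genes 25 rose and 4 fell (26 and 4 adjusted over the list alone), with a median of 0.38, adjusted p = 0.00382 and adjusted p = 0.416 with an estimated correlation.

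The lists that did not pass at stage 12 had camera adjusted p of 0.055 (endoderm), 0.0848 (neuronal differentiation), 0.137 (organizer), 0.176 (germ plasm), 0.217 (DNA replication and pluripotency), 0.279 (p53), 0.298 (Hox), 0.554 (interferon response), 0.667 (neural plate), 0.787 (mesoderm and FGF response) and 0.836 (Polycomb). Of these lists, fry passed endoderm, neuronal differentiation and organizer downwards. It passed germ plasm, DNA replication and interferon response upwards (fry adjusted p of 0.0101 to 0.038). The neural plate list split, with 7 genes higher and 6 lower. zic2.L rose by 1.93 and sox3.S by 1.29, while sox2.L fell by 1.24 and msi1.S by 1.27. Its median was -0.16 and its mean 0.16, with the test down. Of 43 replication genes 17 rose and 4 fell. They included cdt1.L (1.07, with 0.54 for another probe set), pcna.S (0.88), mcm6.2.L (-1.14) and gins3.L (-1.17). Cdt1 is the licensing factor that Geminin binds, and whether the injected form binds it was not tested. Median and test also differed in sign for FGF response (0.12, down) and Polycomb (0.09, down).

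**Figure D2:**
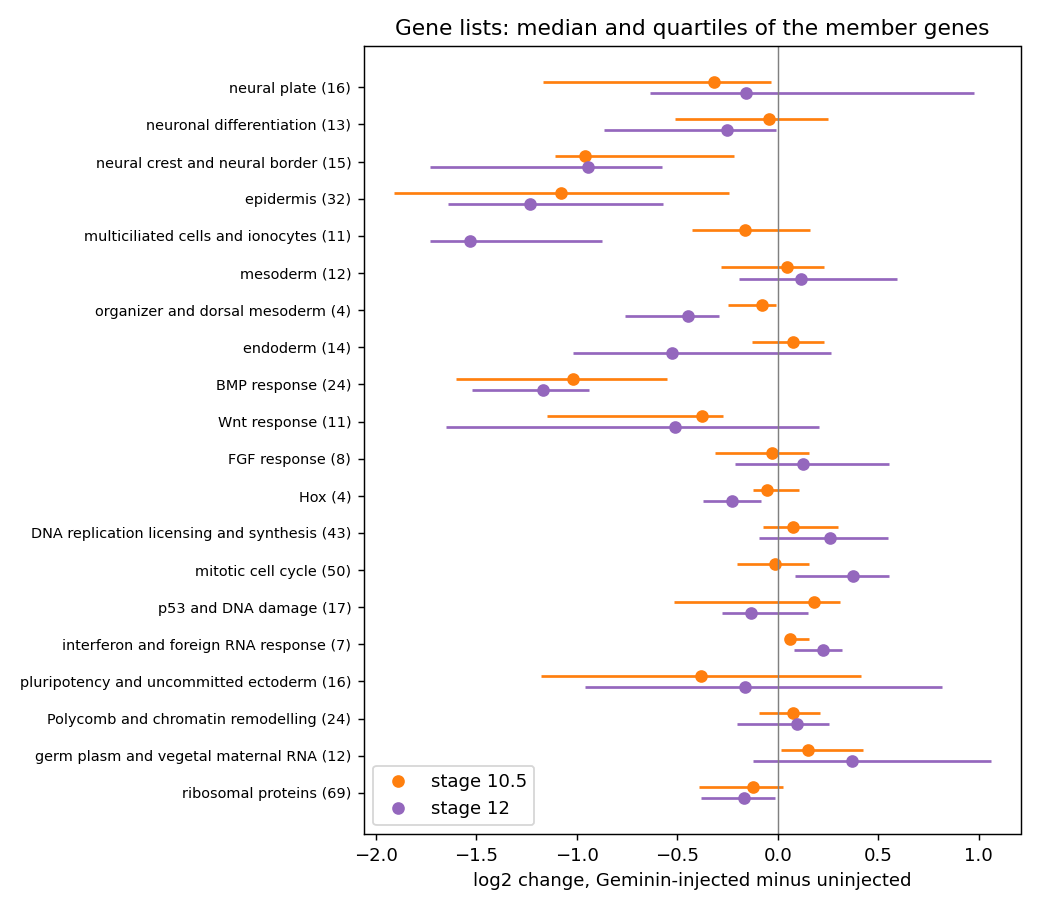
Median (points) and quartiles (lines) of the log2 change, injected minus uninjected, over the member genes of 20 lists at stage 10.5 and stage 12, with the number of genes in parentheses. The epidermis medians are -1.08 and -1.23, and those of multiciliated cells and ionocytes are -0.16 and -1.53.

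The changes at the 2 stages correlated at r = 0.58 and rho = 0.54 across 11618 probe sets, which are not independent replicates. No array is shared between them. Higher at both stages were 230 probe sets, against 90.6 for independent lists, lower at both were 605, against 144.5, and 32 changed in opposite directions. Calls at both stages use the same spread per probe set from the same fit. Part of the overlap beyond independent lists can thus arise without a shared effect.

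**Figure D3:**
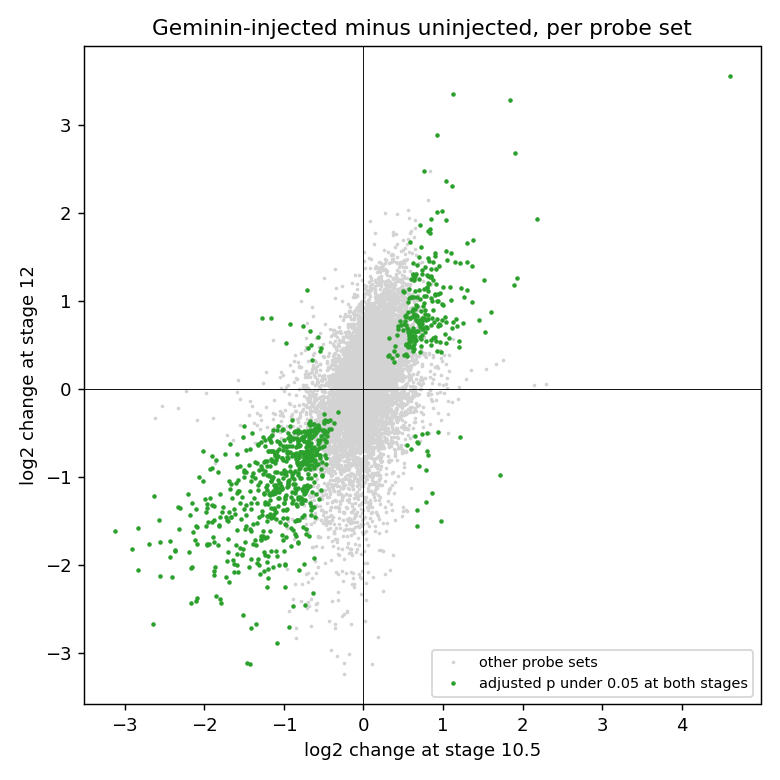
Log2 change per probe set at stage 10.5 (horizontal) and stage 12 (vertical), with probe sets of adjusted p below the threshold at both stages in green. The correlation is 0.58 over 11618 probe sets.

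The injected against uninjected change was lower at stage 12 than at stage 10.5 for 5 of 11 genes of multiciliated cells and ionocytes and higher for 7 of 50 mitotic genes, and no list passed with an estimated correlation. At stage 10.5 itself, 4 of the mitotic genes were higher and 8 lower in injected explants. The difference (stage 12 minus stage 10.5) was -3.23 ± 0.40 (SE, n = 6 pairs) for rsph1.L, -3.01 for dlx2.L, -3.01 for tbc1d24.2.L, -2.83 for ubp1.L and -2.70 for tnni2.S (-1.77 for another probe set). It was 2.34 ± 0.38 for crx.S, 2.23 for ccnb1.S, 2.2 for a probe set of prdm1.S (others 1.19 and 1.74), 2.08 for cyp26a1.S, which degrades retinoic acid, and 1.97 for zic1.S (0.78 for another probe set). Adjusted p over these genes ranged from 0.000766 to 0.00692. Low signal bounds many of these values: uninjected rsph1.L was at 4.40 (log2) at stage 10.5, against a 5th percentile of all probe sets of 4.43. The stage 12 fall of each of the 5 genes with the lowest difference would have ended under that percentile at stage 10.5, so their differences do not show whether they would have fallen there. The same held at stage 12 for the stage 10.5 falls of crx.S, prdm1.S and zic1.S, and not for ccnb1.S and cyp26a1.S. Of 11 genes of multiciliated cells and ionocytes 5 had a lower difference (7 adjusted over the list alone), with adjusted p = 7.44e-07 and adjusted p = 0.233 with an estimated correlation, and 3 of these 5 had too low a signal at stage 10.5 for their stage 12 fall. Of 50 mitotic genes 7 had a higher one (16 adjusted over the list alone), with adjusted p = 1.18e-06 and adjusted p = 0.485 with an estimated correlation. Of 16 neural plate genes 4 had a higher one (7 adjusted over the list alone), with adjusted p = 0.0126 and adjusted p = 0.485 with an estimated correlation. The other 17 lists did not pass, and with an estimated correlation 0 lists passed. Median, mean and test differed in sign for epidermis (0.39, -0.02, down), mesoderm (-0.01, 0.17, up), Wnt response (0.34, 0.07, down), interferon response (0.15, 0.04, down), BMP response (0.11, -0.10, down) and p53 (0.05, 0.13, down), and the medians of BMP response and p53 were -0.23 and -0.07 on the deposited scale. In limma's paired fit 670 probe sets passed, 209 higher and 461 lower, of which 13 and 169 had too low a signal at the other stage by the same measure. Without the replicate block 34 passed, and without the block and the array of conflicting description, an alternative chosen after seeing the data, 0 passed (995 at an unadjusted p under 0.05). Without the stage 10.5 pair of experiment 1, 2 or 3 the count was 310, 183 and 215, without the stage 12 pair of experiment 2 it was 248 (249 without its uninjected array alone), and without that of experiment 3 it was 1033.

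In uninjected explants, epidermal genes (17 of 32) and genes of multiciliated cells and ionocytes (6 of 11) were higher at stage 12 than at stage 10.5, and mitotic (22 of 50) and neural plate genes (11 of 16) were lower. The largest rises were in itln1.L (5.67 ± 0.44, SE, n = 3 arrays per stage), otogl2.L (5.50), tuba1cl.3.L (5.41), agr2.S (4.37) and rsph1.L (4.18). Other probe sets gave 0.92 and 3.23 for otogl2.L and 1.60 and 2.35 for tuba1cl.3.L. Low signal bounds the values of rsph1.L, at 4.40 (log2) at stage 10.5, and of aplnr.S, at 4.36 at stage 12, both under the 5th percentile of all probe sets, and their ranks with them. The largest falls were in ccnb1.S (-4.41 ± 0.38), tdgf1.3.L (-3.64), mex3b.S (-3.39), the apelin receptor gene aplnr.S (-3.24) and cbwd1.1.S (-3.11). Adjusted p from limma over these genes ranged from 4.35e-06 to 0.000211. Lists shifted up were epidermis (17 of 32 higher, 3 lower), multiciliated cells and ionocytes (6 of 11 higher, 1 lower), BMP response (7 of 24 higher, 3 lower) and ribosomal proteins (47 of 69 higher, 1 lower). Lists shifted down were neural plate (11 of 16 lower, 2 higher), replication (18 of 43 lower, 2 higher) and mitosis (22 of 50 lower). Camera adjusted p was 8.86e-06, 0.0012, 0.0248, 2.87e-16, 0.0049, 0.00582 and 1e-04 in that order. With an estimated correlation adjusted p = 0.22, 0.22, 0.394, 0.129, 0.22, 0.116 and 0.186. Adjusted over the list alone, 17 higher and 4 lower in epidermis, 8 and 1 in multiciliated cells and ionocytes, 7 and 3 in BMP response, 52 and 1 in ribosomal proteins, 3 and 11 in neural plate, 2 and 19 in replication and 1 and 24 in mitosis passed. Examples were gata3.S (4.18), ubp1.L (3.05), foxn4.S (2.39) and msx1.S (2.59) among those higher, and sox11.S (-2.92), zic2.L (-2.82), sox3.S (-2.56), cdc6.S (-2.62), cdt1.L (-2.22, with -0.84 for another probe set) and ccnb2.L (-1.8) among those lower. The other 13 lists did not pass with camera, and fry called 15 lists. For Wnt response the median was 0.10, or -0.16 on the deposited scale, the mean -0.56 and the test down.

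Of 11618 probe sets 3683 passed between the uninjected stages, 1762 higher and 1921 lower, or 47.8% higher, and 3219 passed without the library labelled uninjected, stage 12, experiment 3. The uninjected stage 12 arrays of experiments 2 and 3 correlated at 0.990. SEs and p between the uninjected stages could thus rest on fewer than 3 independent stage 12 arrays. On the deposited scale 1375 passed, 35.9% of them higher, and with median centring 3859 passed, 62.2% of them higher. The median change of all probe sets was -0.04 after quantile normalisation, -0.22 on the deposited scale and 0.12 with median centring, so directions of small changes between stages are relative to the scaling.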

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

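The tests of the gmnn.L signal, of shared arrays, of an even delay and of low signal (for the list and for all differences between stages) were chosen after the result was seen. Of the results reported, 670 probe sets were selected because the injected against uninjected change differed between the stages by the test of that difference. In 10 splits of the 6 pairs, only 1 (the real one) gave as many, and the highest other count was 0. These splits are too few for a share under 0.05.

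Among genes named, the difference (stage 12 minus stage 10.5, log2) was lower for rsph1.L (-3.23), dlx2.L (-3.01), tbc1d24.2.L (-3.01), ubp1.L (-2.83), tnni2.S (-2.70, with -1.77 for another probe set), sox7.L (-2.54), cfap52.S (-2.36), itln1.L (-2.33), ppl.L (-2.10), fzd10.S (-2.03), ca12.L (-1.94), agr2.L (-1.92), agr2.S (-1.92), plpp3.S (-1.80), dnai1.L (-1.74), myc.S (-1.71, with -1.11 and -1.24 for other probe sets), slc38a2.L (-1.70), foxn4.S (-1.70), orc4.L (-1.56), ets1.S (-1.45), zfp36l2.1.S (-1.42), tll1.S (-1.30), hunk.L (-1.30), smad6.L (-1.22), ccng2.L (-1.21), hand2.S (-1.18), myc.L (-1.15), msx1.S (-1.01) and foxa1.S (-0.80).

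It was higher for crx.S (2.34), ccnb1.S (2.23), prdm1.S (2.2 and 1.74 for its probe sets), cyp26a1.S (2.08), zic1.S (1.97), otx1.L (1.73), pc.1.L (1.72), ccna1.L (1.65), vegt.L (1.57), krt70.L (1.51), sesn1.L (1.48 and 1.27 for its probe sets), tsen54.L (1.45), dlx3.S (1.42), tmem169.L (1.34), irx1.L (1.32), plin2.S (1.2), ccnb3.S (1.18), irx2.L (1.15), wee2.S (1.1), gadd45g.S (1.02), ccnb1.2.L (0.79), cdt1.L (0.77) and rps23.L (0.59).

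The first pattern is the gmnn.L intensity of 4576 in the library labelled uninjected, stage 12, experiment 3. A swap of the arrays of that pair is argued against by a correlation of 0.774 between its differences and the mean of the other stage 12 pairs. RNA of injected explants mixed in at the share that gmnn.L gives, 32.7%, would have shrunk the pair's median change to 0.654 of that of experiment 2, and 0.782 was seen, with an SD of such ratios at stage 10.5 of 0.372. That SD was taken over ratios together with their reciprocals, so it does not measure the spread between experiments. Mixing stays open, since gmnn.L was the brightest probe set on the injected arrays of experiments 2 and 3 and a saturated reading would make the true share smaller. No biological explanation was tested.

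The second pattern is that stage 12 changes ran against the changes of uninjected explants from stage 10.5 to 12, with opposite signs in 2306 of the 2369 probe sets called in both (97.3%). Correlations of the stage 12 changes with no array shared were -0.565, -0.688 and -0.522 (-0.627 and -0.505 for experiments 2 and 3 when neither of their closely similar uninjected arrays entered the stage change), which argues against shared arrays as the whole cause. The stage 10.5 changes also ran against the uninjected stage change, at -0.374, -0.364 and -0.113 for experiments 1, 2 and 3 with no array shared. Delay as a cause of the stage 10.5 changes was not tested. A single even delay of the whole explant as the whole cause was tested with probe sets beyond the uninjected levels of both stages at stage 12. Under such a delay each would need to oscillate, since injected stage 12 explants had moved past the uninjected stage 10.5 level. Candidates (703 to 1016 probe sets) changed at least 1.5-fold the same way in both of 2 stage 10.5 pairs. They were tested against the uninjected stage 10.5 array of the left-out pair (limma, larger of both one-sided p, adjusted). For all 3 choices of that pair, 35 probe sets passed (34 lower, 1 higher). Each choice rests on 1 uninjected stage 10.5 array, so the spread comes from other groups. All 3 choices also share the stage 12 arrays. The 35 probe sets thus cannot decide on an even delay, which stays open. A delay that differs between genes is a candidate explanation that also stays open. Of the stage 12 changes, 6.61% (316 of 4781, 2.47% to 10.3% without a pair) passed as beyond the uninjected stage 10.5 level. The test was an unpaired limma fit of injected stage 12 against uninjected stage 10.5 explants, at adjusted p under 0.05. The share lay between the limits of 5% and 10% set for delay as the whole cause. Changes that did not pass are not shown to lie within that level, so the share can be too low. A delay of either kind, an effect of Geminin on single genes and an effect of injection itself cannot be told apart here.

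The third pattern is that 9 of 11 genes of multiciliated cells and ionocytes fell at stage 12, and the change of 5 was lower there than at stage 10.5. A technical explanation is low signal at stage 10.5 leaving no room for a fall. Of the 10 members with a lower value at stage 12, 3, or 30 percent, would have ended under the 5th percentile of all probe sets had they fallen as far from their uninjected stage 10.5 level, which leaves this open for the list. These 3 are among the 5 members whose change differed between stages. The cell types that form between the stages are an untested biological explanation.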

How the results depend on the processing

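The alternatives that average experiments 2 and 3 of stage 12, or drop the block together with an array, were chosen after seeing the data. Without the replicate block 262 probe sets passed at stage 10.5, 1509 at stage 12 and 34 for the difference between stages, instead of 1205, 4781 and 670. Without the block and the array of conflicting description 967 passed at stage 12 and 0 for the difference (limma, 995 at an unadjusted p under 0.05, 1 array fewer), and without the block and the array of high gmnn.L signal 1162 passed at stage 12. The compared groups alone gave 1830 at stage 10.5. For the difference between stages, leaving out the lowest 50% of probe sets gave 379 (fewer probe sets tested) and pseudocount 1 gave 437. The deposited scale gave 1375 for the uninjected stages. The count of consistent pairs was 333 with pseudocount 64 and 180 at 2-fold at stage 10.5, and 895 and 519 at stage 12, instead of 611 and 1469. With an estimated correlation 0 gene lists were shifted at stage 10.5 and 0 at stage 12, and fry called 13 at stage 12. Where no construction is named, the cause was not tested.

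Leaving out 1 replicate, with fewer arrays, gave 454 to 779 probe sets at stage 10.5, 3283 to 4416 at stage 12, 183 to 1033 for the difference between stages, 2811 to 3219 for the uninjected stages, and 703 to 1016 and 1685 to 2458 consistent changes at the 2 stages. Averaging experiments 2 and 3 gave 4085 at stage 12 and 563 for the difference. Of the gene lists, endoderm passed at stage 12 without the block and without a filter, neuronal differentiation without a filter, and Wnt response did not pass without experiment 3. With fry, pluripotency (adjusted p = 0.0918) and ribosomal proteins (0.0826) did not pass at stage 10.5. At stage 12 fry also passed DNA replication (0.0172), germ plasm (0.0101), interferon response (0.0275), endoderm (0.0101), organizer (0.038) and neuronal differentiation (0.038). No gene named, and no list at either stage, changed direction where it passed in either of the fits compared. Over all called probe sets, 1 turned at stage 12 in each fit without the block and an array, and for the uninjected stages 9 turned on the deposited scale and 38 with median centring. A replicate block gave 4673 for the uninjected stages. Low signal bounds part of the difference between stages: for 169 of the 461 lower and 13 of the 209 higher differences, the fall at one stage would have ended under the 5th percentile of all probe sets at the other.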

Other observations

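The stage position, the comparison of gene copies and the closeness of arrays were not planned before the data were examined. On probe sets that separated the uninjected stages, chosen on other arrays than those measured, injected stage 12 explants had covered 31.4%, 37.4% and 56.2% of the change from uninjected stage 10.5 to uninjected stage 12 in experiments 1, 2 and 3. Each value is the median injected shift divided by the median uninjected shift, averaged over the choices of uninjected stage 10.5 array. The uninjected value of experiment 3 comes from the library with high gmnn.L signal. Among 12 germ plasm and vegetal maternal genes, 6 were higher and 1 lower in injected than in uninjected explants at stage 12. The list did not pass with camera (adjusted p = 0.176) and passed upwards with fry (adjusted p = 0.0101). The maternal T-box gene vegt.L was 1.99 higher, and plin2.S was 1.69 higher.

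Over 794 genes with both the .L and the .S copy tested, the injected against uninjected changes of the copies correlated at 0.633 at stage 10.5 and 0.669 at stage 12, across genes, which are not independent replicates. Both copies passed for 50 genes at stage 10.5, 49 in the same direction, and for 222 at stage 12, 208 in the same direction. Only 1 copy passed for 106 genes at stage 10.5 and for 303 at stage 12, and a difference between copies was not tested. Cross-hybridisation between copies was not tested.

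At stage 12 the arrays of experiments 2 and 3 were closer to each other than any pair was, with correlations of 0.990 between the uninjected and 0.982 between the injected arrays. If they share embryos, the 3 pairs of stage 12 are not all independent, and SEs, p and counts over 3 pairs there are too favourable. The same would then hold for the comparison of the uninjected stages.

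Other groupings were counted for each fit, and 4 or 10 splits are too few for a share under 0.05. In the paired fits 1 of 4 splits that part all 3 pairs, the real one, gave as many probe sets at stage 10.5 (1205, highest other 0) and at stage 12 (4781, highest other 0). Without the block 1 of 10 splits did so, with 262 against a highest other of 2 at stage 10.5 and 1509 against 0 at stage 12. Between the uninjected stages 1 of 10 splits did so, with 3683 against 0. For gene lists 2 of 4 splits gave as many as the real one at each stage. At stage 10.5 the real split shifted 7 lists, and turning the pair of experiment 1, 2 or 3 shifted 0, 1 and 9. At stage 12 the real split shifted 7, and turning the pair of experiment 1, 2 or 3 shifted 1, 8 and 6. At each stage 1 of the 3 turnings thus reached the real count. A turned split keeps the real sign in 2 of 3 pairs, so its counts are not those of arrays without an effect. For probe sets, turning a pair lowers the count wherever pairs move alike, whatever the cause.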
